A study of Rattus norvegicus with 9 samples.

How the data were processed

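Messenger RNA from snap-frozen liver of 9 individual ovariectomised Wistar rats was sequenced as paired-end, strand-specific libraries, per the labels' protocols, with 1 library per animal. The deposited table holds whole-number read counts per gene for 24496 genes with their symbols and Ensembl identifiers, not normalised by the authors. The submitters' processing notes name STAR, edgeR, DESeq2 and the rat genome build rn6, without versions or the role of each tool; the annotation and the strand setting of the counting are not given in the sources used here. Each of the 9 count columns was matched to a sample by its label. The reference gene table at hand was of another build, so no coordinates are given, and gene names are those in the deposited table. In it 22 symbols had turned into dates and were not named. There were 8868 genes listed at 0 in all libraries, among them the 13 mitochondrially encoded genes, so a gene listed at 0 cannot be taken as not expressed.

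The counts of 4 FSH and 5 vehicle libraries were compared in R 4.3.3 with edgeR 4.0.16, using the quasi-likelihood F-test (2-sided), trimmed mean of M values scaling, filtering of low counts by group and Benjamini-Hochberg adjustment over the 11924 genes kept, which hold 99.96% of all counts. The threshold was an adjusted p (FDR) of 0.05. Fold changes are FSH over vehicle on the log2 scale, and their standard errors were derived from the fold change and the F statistic. CPM values are counts divided by the library total, scaled by the same factors and expressed per 1e6 counts. A single read is worth 0.0349 to 0.0518 CPM across libraries. Libraries of the same group differed far beyond counting noise (smallest chi-square per degree of freedom 27.1), so none was a repeat of another.

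Before the data were examined, 34 gene lists of pathways, cell types and hormone axes were fixed, of which 33 had at least 3 tested genes. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and also with an estimated correlation and with fry. Named genes also followed a rule fixed then: genes of the hormone axis (Fshr, Lhcgr, Esr1, Ghr, Igf1 and Prlr among them) in any case; the 12 highest and 12 lowest fold changes past the threshold with a mean of at least 1 CPM and a proper symbol, or all if fewer; the 10 smallest p-values; and from each list the members past the threshold, at most 4, or else the 2 with the smallest p. Members that passed when adjusted over a list alone were named in addition, after their values were seen. Some genes that the rule takes are not reported here.

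The steps were tested on simulated counts for this comparison with 11924 genes, 200 of them changed. Of those changed by 0.5, 1 and 2 on the log2 scale, 19.7%, 79.1% and 94.0% were called in the right direction, and 5 of 11704 unchanged genes were called. Camera called the 1 simulated list that was shifted and 0 of 32 unshifted lists, whose genes were simulated as independent.

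Alternatives were a replicate block, DESeq2 1.42.0, limma-voom with sample quality weights, size factors of DESeq2's kind, total counts alone, no filter, at least 1 CPM in at least 4 samples, 1 surrogate variable from sva 3.50.0, an FDR of 0.10, a log2 fold change of at least 1, and leaving out each animal. Thinning all libraries to 19295580 counts, the total of the shallowest, was added after seeing the data. Alternatives meant for normalised values did not apply to counts.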

Results

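Liver RNA was sequenced from 9 female Wistar rats, 1 library per animal. The rats ate a western diet from 10 weeks of age, were ovariectomised after 6 weeks of it and received degarelix, an antagonist of the gonadotropin-releasing hormone receptor that lowers pituitary secretion of luteinising hormone and follicle-stimulating hormone (FSH). Osmotic pumps then delivered vehicle in 5 rats or FSH at 6 µg per kg per day in 4 rats. Food was limited for 12 days and free for 7 days, and livers were taken at 19 weeks of age after a 4 h fast. Library totals lay between 19295580 and 28672439 counts in the vehicle group and between 23430807 and 27008941 counts in the FSH group. The comparison asks how FSH affects liver transcripts when ovarian hormones and the animals' own gonadotropins are low.

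Crat, Cpt1a and Acot4 were higher with FSH and Tfg was lower. Crat (ENSRNOG00000018145), which encodes carnitine acetyltransferase, stood at 58.0 ± 10.8 CPM (counts scaled to library size; mean ± SD, n = 4) with FSH and 19.6 ± 4.05 CPM (n = 5) with vehicle. Its log2 fold change was 1.57 (SE 0.17, edgeR adjusted p = 0.0145). Cpt1a (ENSRNOG00000014254), the carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondria, rose from 337 ± 69.6 to 833 ± 110.1 CPM, a log2 fold change of 1.31 (SE 0.17, edgeR adjusted p = 0.0337). Acot4 (ENSRNOG00000046864), a peroxisomal acyl-CoA thioesterase, rose from 21.8 ± 3.38 to 43.4 ± 1.99 CPM (log2 fold change 1.00, SE 0.11, edgeR adjusted p = 0.0145). Acot4 belongs to a family of similar neighbouring genes, and its count is uncertain where reads were shared among them. Tfg (ENSRNOG00000001633), which acts in transport from the endoplasmic reticulum, fell from 43.8 ± 0.886 to 32.5 ± 0.951 CPM (log2 fold change −0.43, SE 0.06, edgeR adjusted p = 0.0337). In each of these 4 genes every FSH library lay outside the range of the vehicle libraries.

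**Figure D1:**
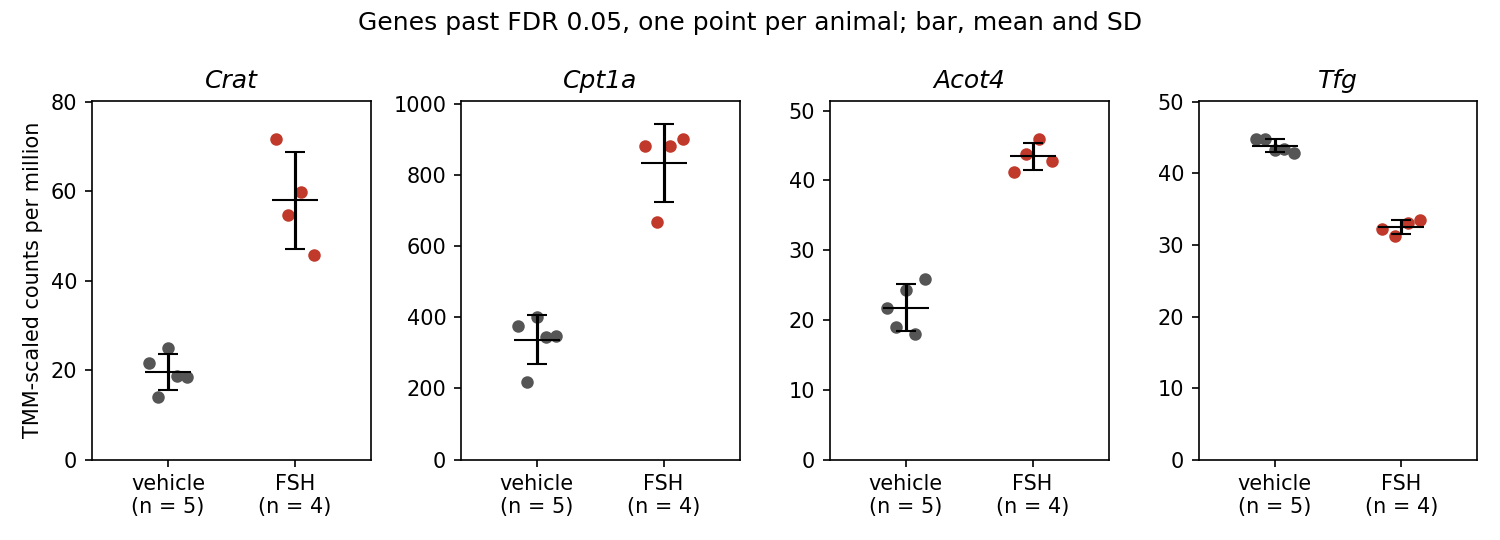
CPM scaled by the trimmed mean of M values (vertical axes, starting at 0) of the 4 genes past FDR 0.05, with 1 point per animal (grey, vehicle; red, FSH) and the mean and SD as bars. The FSH and vehicle points do not overlap in any panel, and Cpt1a averages 833 CPM with FSH and 337 CPM with vehicle.

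These were the only genes past FDR 0.05 among 11924 tested with edgeR's quasi-likelihood test, 3 higher and 1 lower with FSH. At an unadjusted p under 0.05 there were 1378 genes, where chance alone gives about 596 on average. How widely that number varies by chance among correlated genes was not measured. DESeq2's Wald test called 109 genes higher and 67 lower, including the same 4 genes. No gene passed in edgeR without vehicle replicate 1, vehicle replicate 4, FSH replicate 1 or FSH replicate 3. In total 1 gene passed without FSH replicate 4, 2 without vehicle replicate 3 and 2 without vehicle replicate 5. The fold changes moved little: over the 9 fits that each left out 1 animal, that of Crat lay between 1.45 and 1.68 and that of Cpt1a between 1.18 and 1.39, with adjusted p up to 0.0948 and 0.158. That of Acot4 lay between 0.93 and 1.07, with adjusted p up to 0.0948. Crat and Acot4 each lost their call in 5 of these 9 fits and Cpt1a in 7. Cpt1a also lost it with 1 surrogate variable in the model (edgeR adjusted p = 0.0811). Tfg lost its call in each of those 9 fits, at adjusted p between 0.0792 and 0.158, with a fold change between −0.45 and −0.42.

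Several further genes missed the threshold narrowly. Sec23a, a coat protein of vesicles leaving the endoplasmic reticulum, had a log2 fold change of 0.46 (SE 0.07), Hsdl2, a peroxisomal dehydrogenase-like protein, 0.86 (SE 0.12), Sik2, a salt-inducible kinase, 0.58 (SE 0.08), and Hn1l −0.56 (SE 0.08), each at an edgeR adjusted p of 0.0515. Vps13c, a lipid transfer protein, followed with 0.49 (SE 0.07, edgeR adjusted p = 0.0633), and Krt8, a keratin of hepatocytes and bile ducts, with −0.42 (SE 0.07, edgeR adjusted p = 0.0711).

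Fatty acid oxidation and ketogenesis genes rose together with FSH (28 of 29 higher, median log2 fold change 0.28, camera adjusted p = 8.54e-11). With an estimated correlation the call was lost (adjusted p = 0.305), and the list did not pass in fry's directional test (adjusted p = 0.075). Cpt1a passed over all genes, and 12 members passed when adjusted over the list alone, all higher. Besides Cpt1a these included Creb3l3, a hepatic transcription factor (0.37, SE 0.07), Eci1, an enoyl-CoA isomerase (0.74, SE 0.14), and Cpt2 (0.53, SE 0.14). Cyp4a2 and Acot2, at 0.91 (SE 0.19) and 0.86 (SE 0.19), were also among them, and both have close relatives that may share their reads. Fatty acid and triglyceride synthesis genes fell together (20 of 22 lower, median −0.33, camera adjusted p = 0.000136). None passed over all genes or when adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.548). The smallest p-values in that list belonged to Thrsp, a regulator of lipogenesis (−0.57, SE 0.19), and Srebf1, the transcription factor SREBP-1 (−0.56, SE 0.22).

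Lipid droplet genes moved in part. In the list of fatty acid uptake, lipid droplets and lipoproteins, 14 of 24 members had higher fold changes (camera adjusted p = 0.0675), and 3 passed when adjusted over the list alone, none over all genes. These were the droplet coat proteins Plin5 (0.99, SE 0.16) and Plin2 (0.75, SE 0.21) and the droplet-forming protein Fitm2 (0.55, SE 0.12). Plin2 varied among the FSH animals, at 188, 273, 107 and 158 CPM in replicates 1 to 4. Its value in FSH replicate 3 lay within the range of the vehicle libraries (98.7 to 119 CPM). Cholesterol synthesis and uptake genes did not pass (14 of 23 lower, camera adjusted p = 0.186), with values of −0.86 (SE 0.31) for Mvd and −0.62 (SE 0.26) for Mvk, both enzymes of the mevalonate pathway. That list passed without vehicle replicate 3, vehicle replicate 5 or FSH replicate 3 (adjusted p = 0.0139, 0.0442 and 0.00288). Nor did bile acid synthesis and transport (adjusted p = 0.45, Akr1d1 −0.36, SE 0.12, and Acox2 −0.45, SE 0.16) or glucose metabolism and insulin signalling (adjusted p = 0.45, Khk −0.30, SE 0.08, and Gys2 0.58, SE 0.18). Nuclear-encoded respiratory chain genes fell by a small amount, with 58 of 61 lower and a median of −0.09 (camera adjusted p = 4.36e-06, and adjusted p = 0.548 with an estimated correlation). No member passed when adjusted over the list alone, and Cox8a (−0.21, SE 0.08) and Ndufa8 (−0.24, SE 0.10) had the smallest p-values. The 13 mitochondrially encoded genes were listed at 0 in every library and could not be tested.

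The hormone receptors gave few measurable values. Fshr and Lhcgr were listed at 0 in all 9 libraries, and Esr1 was not analysed here. Ghr, the growth hormone receptor, was at 529 ± 175 CPM with FSH and 501 ± 41.8 CPM with vehicle (log2 fold change 0.08, SE 0.18, edgeR adjusted p = 0.904), and Igf1 at 330.3 ± 78.5 and 338 ± 54.4 CPM (−0.03, SE 0.17, edgeR adjusted p = 0.963). Prlr, the prolactin receptor, had a log2 fold change of 0.58 (SE 0.25, edgeR adjusted p = 0.418), which was 0.16 without FSH replicate 1. In the axis list, Shbg passed when adjusted over the list alone (1.25, SE 0.30), at 0.841 and 0.355 CPM, Socs2 had 1.40 (SE 0.47), and the list did not pass (camera adjusted p = 0.136). Female-type liver genes had higher fold changes as a list (4 of 4 tested, median 0.45, camera adjusted p = 0.0468). The call was lost with an estimated correlation (adjusted p = 0.305) and without vehicle replicate 2, FSH replicate 1 or FSH replicate 4 (adjusted p = 0.0872, 0.0793 and 0.068). A1bg passed when adjusted over the list alone (1.25, SE 0.36). Cyp2c12, the most abundant of the 4, hardly differed, at 3024 CPM with FSH and 2869 CPM with vehicle (0.08, SE 0.13, edgeR adjusted p = 0.863). Male-type genes did not pass (camera adjusted p = 0.193, with Cyp2c13 −0.67, SE 0.34, and −0.42 without vehicle replicate 4, and Dhrs7 −0.19, SE 0.15, and −0.10 without FSH replicate 1 or −0.30 without FSH replicate 2), and neither did early genes that respond to cyclic AMP (adjusted p = 0.136, Jun 0.74, SE 0.29, and Junb 0.67, SE 0.29, which was 0.30 without FSH replicate 2).

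Sinusoidal and vascular endothelial markers rose with FSH (12 of 14 higher, median 0.28, camera adjusted p = 0.000136), a call lost with an estimated correlation (adjusted p = 0.548). The lectin Clec4g (0.61, SE 0.13), the scavenger receptor Stab1 (0.43, SE 0.11) and the receptor Flt4 (0.51, SE 0.13) passed when adjusted over the list alone. Stellate cell and fibrosis genes fell (19 of 21 lower, median −0.20, camera adjusted p = 0.000887), a call lost with an estimated correlation (adjusted p = 0.291). The collagen gene Col3a1 (−0.45, SE 0.11), Ctgf (−0.76, SE 0.21) and the collagen cross-linking enzyme Lox (−1.87, SE 0.55) passed when adjusted over the list alone. Cell cycle genes also fell (16 of 18 lower, median −0.41, camera adjusted p = 2.4e-05, and adjusted p = 0.305 with an estimated correlation). Among them the replication helicase subunit Mcm5 passed when adjusted over the list alone (−1.73, SE 0.43), and Mcm6 had −1.19 (SE 0.40). Of all tested genes in these 3 lists, none passed over all genes.

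**Figure D2:**
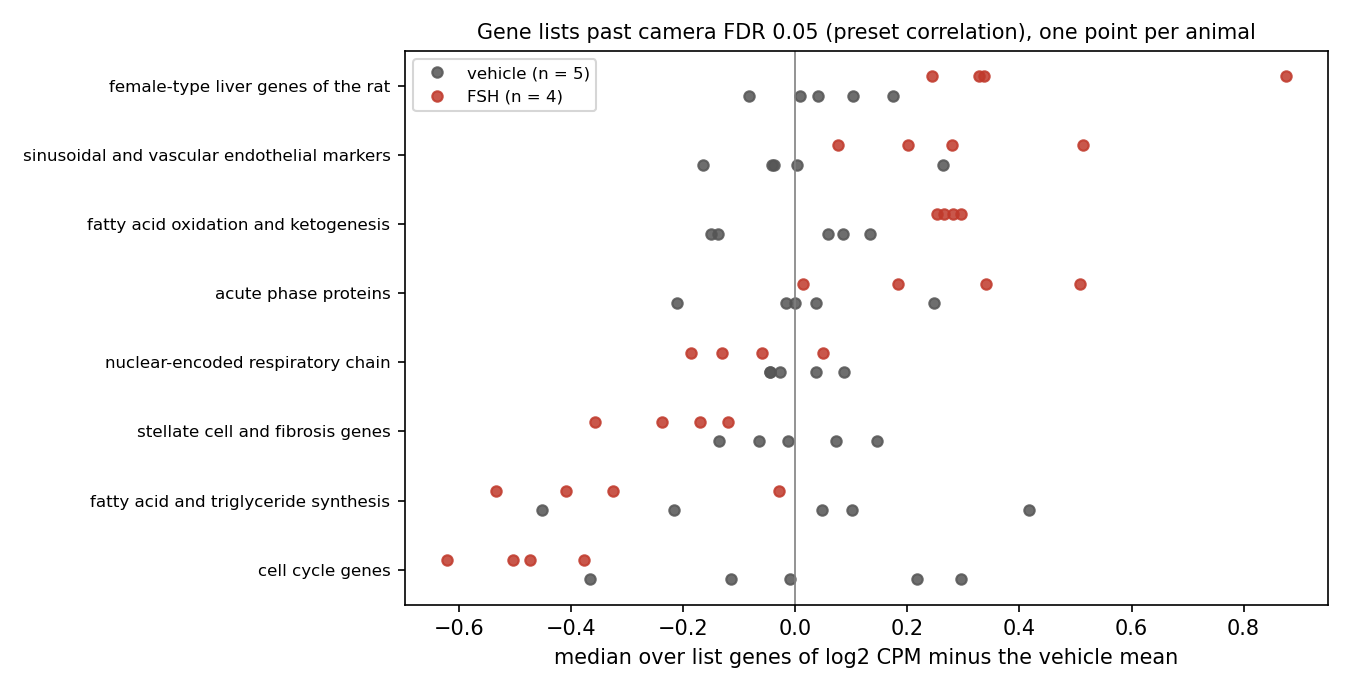
Median over the genes of each list of log2 CPM minus the mean of the vehicle libraries (horizontal axis), with 1 point per animal (grey, vehicle; red, FSH), for the 8 lists that passed camera at FDR 0.05 with a preset correlation. The 4 FSH points of fatty acid oxidation and ketogenesis lie between 0.25 and 0.30, above every vehicle point. The points of both groups overlap for acute phase proteins and for fatty acid and triglyceride synthesis. They also overlap for respiratory chain genes, endothelial markers, and stellate and fibrosis genes.

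Other cell types did not pass. Camera adjusted p-values were 0.0675 for cholangiocyte markers (Cftr −0.74, SE 0.34, and Krt7 −0.76, SE 0.41), 0.915 for hepatocyte markers (Fgb 0.55, SE 0.18) and 0.915 for Kupffer cell and macrophage markers (Timd4 0.80, SE 0.62, and Gpnmb −0.49, SE 0.40). They were 0.301 for neutrophil markers (S100a9 0.56, SE 0.45, and Fcnb 0.27, SE 0.37) and 0.688 for T, NK and B cell markers (Nkg7 −0.33, SE 0.27). Erythroid and blood genes did not pass (adjusted p = 0.136), but Hbb, a haemoglobin gene, passed when adjusted over the list alone, at 184 ± 106 CPM with FSH and 63.5 ± 18.6 CPM with vehicle (1.54, SE 0.35), and Hba-a2 had 0.80 (SE 0.38), which was 0.185 without FSH replicate 3. Leaving out 1 animal also moved Timd4 (−0.025 without FSH replicate 2), Gpnmb (−0.23 without vehicle replicate 1), S100a9 (0.36 without vehicle replicate 2 and 0.35 without FSH replicate 3), Fcnb (0.10 without vehicle replicate 3 and 0.71 without vehicle replicate 4), Nkg7 (−0.14 without vehicle replicate 4) and Cftr (−1.20 without FSH replicate 2). The list of adjacent tissues did not pass (adjusted p = 0.461), and Fabp2 had −0.21 (SE 0.24), which was −0.06 without vehicle replicate 1 and −0.34 without FSH replicate 2.

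Acute phase proteins rose with FSH (17 of 20 higher, median 0.25, camera adjusted p = 0.00177), without any member past the threshold over all genes or when adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.548). The fibrinogen chain Fga had 0.69 (SE 0.21) and the inhibitor subunit Itih4 0.41 (SE 0.13). Cytokines and chemokines (adjusted p = 0.688, Cxcl1 2.28, SE 1.02, and Il1b 0.58, SE 0.26) and interferon response genes (adjusted p = 0.427, Rsad2 0.51, SE 0.24, and RT1-Bb 0.30, SE 0.20) did not pass. The value of Cxcl1 was 0.44 without FSH replicate 2, which stood at 53.8 CPM, and in FSH replicate 1 it was at 0.715 CPM, below every vehicle library. That of Il1b was 0.37 without FSH replicate 3, and that of RT1-Bb 0.18 without FSH replicate 2 and 0.45 without vehicle replicate 4. In the cytokine list the median was −0.05 and the mean 0.03, with a downward test. In the interferon, Kupffer cell and hepatocyte lists the medians of −0.02, −0.03 and −0.01 were opposite to the upward test, as was the mean of −0.02 in the T, NK and B cell list.

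Stress, clock and zonation lists did not pass either. In the endoplasmic reticulum and integrated stress response list (adjusted p = 0.667), Fgf21 (0.90, SE 0.23) and the transcription factor Xbp1 (0.83, SE 0.23) passed when adjusted over the list alone, while 15 of 23 members were lower. Fgf21, a secreted metabolic hormone, also passed when adjusted over the hepatokine list alone, where the list's adjusted p was 0.193. In that list Igfbp2 had 1.67 (SE 0.62), which was 0.79 without FSH replicate 1 (17.1 CPM). Drug and xenobiotic genes (adjusted p = 0.186) held a transporter, Abcb1a (0.58, SE 0.09), and a glutathione transferase, Gsta2 (−1.24, SE 0.31), that passed when adjusted over the list alone in opposite directions. Camera adjusted p-values were 0.461 for antioxidant genes (Gclc −0.55, SE 0.23, and Mt1 0.81, SE 0.39), 0.111 for heat shock genes (Hsph1 −0.73, SE 0.28, and Hspa8 −0.93, SE 0.42) and 0.193 for clock genes (Cry2 −0.32, SE 0.10, and Bhlhe40 0.31, SE 0.11). They were 0.186 for pericentral genes (Nkd1 −0.36, SE 0.14, and Oat −0.80, SE 0.37), 0.136 for periportal genes (Arg1 −0.32, SE 0.17, and Gls2 −0.23, SE 0.15) and 0.186 for cytoplasmic ribosomal proteins (Rps4x −0.35, SE 0.11, and Rpl17 −0.28, SE 0.11). Values that moved by over 1.5 times on leaving out 1 animal included Gclc (−0.33 without vehicle replicate 2), Mt1 (0.38 without FSH replicate 4), Hsph1 (−0.38 without vehicle replicate 3) and Oat (−0.38 without vehicle replicate 1). Counts of Hspa8 (1.04 and 1.99 CPM) and Rps4x (4.67 and 5.95 CPM) are uncertain, since both have many near-identical copies in the genome.

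Altogether 8 of 33 tested lists passed with camera's preset correlation, 4 upward and 4 downward, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05. In fry's directional test 0 lists passed. Its mixed test, which asks for changes of members in either direction, passed 8 lists, not all of them the same as camera's. Among them were lipid droplet genes (fry mixed adjusted p = 6.31e-07), fatty acid oxidation genes (0.000776) and drug genes (0.018). That test gives a list no direction. Of the 8 lists past camera with the preset correlation, 7 kept their call in each fit that left out 1 animal, and without vehicle replicate 4 the count was 16 lists. In all, 14 lists that had not passed did so on leaving out some animal. Besides cholesterol synthesis and Kupffer cells, these were drug, neutrophil, heat shock and pericentral genes (each adjusted p = 0.0266 without vehicle replicate 4), ribosomal, periportal, axis and erythroid genes (0.0326, 0.0353, 0.0444 and 0.0491 without the same animal), early cyclic AMP genes (0.0107 without vehicle replicate 2), interferon genes (0.0439 without vehicle replicate 1), lipid droplet genes (0.0038 without FSH replicate 3) and cholangiocyte markers (0.00744 without FSH replicate 2). Kupffer cell markers passed in the reversed, downward direction without vehicle replicate 2 (adjusted p = 0.0236). Some lists passed without other animals too: lipid droplet genes without vehicle replicate 5 (0.0335), axis genes without FSH replicate 3 (0.0364), drug and erythroid genes without FSH replicate 2 (0.03695 each), periportal genes without FSH replicate 4 (0.041), and cholangiocyte markers without vehicle replicate 1 or 5 (0.0458 and 0.0174). Of the 4 genes past the threshold, 0 moved by over 1.5 times in these fits. FSH replicate 1 stood apart from the other libraries: Alb took 19.4% of its counts and 10.5 to 16.7% in the others, Prlr was at 614 CPM, and its score on the second principal component was 33.8.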

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

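Tests of depth, of cell composition, of neighbouring tissue and of the time since the last meal were chosen only after the result was seen. Within each group, the highest or lowest animal was compared with the spread of the others for 220 sets of values, of which 13 stood apart, where chance gives about 11. For named genes, these were Prlr in FSH replicate 1 (614 CPM, next 286), Cpt1a in FSH replicate 2 (lowest, 669 CPM, next 882), Ndufa8 in FSH replicate 4 (101 CPM, next 83.5) and Rps4x in FSH replicate 2 (lowest, 4.14 CPM, next 4.82). In the vehicle group they were Fcnb in replicate 4 (0.868 CPM, next 0.419), Gclc in replicate 2 (291 CPM, next 165), Hsph1 in replicate 3 (325 CPM, next 143) and Oat in replicate 1 (1571 CPM, next 656). For list medians of log2 CPM relative to the vehicle mean, they were glucose metabolism and insulin signalling in FSH replicate 3 (−0.14, lowest), adjacent tissue markers in FSH replicate 3 (0.19, lowest), cytokines and chemokines in vehicle replicate 2 (−0.36, lowest), and male-type genes (−0.75, lowest) and female-type genes (0.88, highest) in FSH replicate 1.

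FSH replicate 1 holds 3 of these 13 values, with female-type genes high and male-type genes low. They are not independent, since Prlr is itself in the female-type list. The male-type median rests on 3 genes, of which Cyp2c13 was at 0.596 CPM in this library. Bile duct tissue in the piece sampled is argued against, since the cholangiocyte median of this library lay below the highest of the other FSH libraries (difference −0.50). As a hypothesis, this animal may have had a more female-type liver profile. On 4 genes not examined before, the mean of female-type minus male-type deviations was 0.78 in this library and at most 0.54 in the others. That score met the criterion set in advance but rests largely on Hsd11b1 (−2.42): without this gene it was 0.23, no longer the highest of the libraries (0.25 in FSH replicate 4 and 0.23 in vehicle replicate 4), and Trim24 (−0.04) did not go that way. The genes are too few to decide, and the origin of this profile stays open.

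Fatty acid oxidation genes were higher with FSH in all 4 animals. Differing depth as the whole cause is argued against: with log2 total counts in the model of the list median per library, the coefficient of FSH was 0.29 (SE 0.07), compared with a difference of 0.28 without it, and the totals of all 4 FSH libraries lay within the range of the vehicle libraries. A larger hepatocyte share is argued against too, since the list rose by 0.29 (SE 0.09) more than hepatocyte markers did. A longer time since the last meal stays open: 7 gluconeogenic and amino acid genes, 2 of them also members of fixed lists, had no net direction that could be detected (fry p = 0.982, exact permutation p of their median = 0.698), and a p of this size does not exclude a shift. Other genes that feeding may change were not part of that test. Irs2 (0.94, SE 0.39) and Igfbp1 (0.95, SE 0.50) were higher with FSH. Tat was lower (−0.88, SE 0.31) and Pck1 hardly differed (0.20, SE 0.27). None of them passed over all genes, and the lower fatty acid and triglyceride synthesis genes were not weighed here either. An effect of FSH on these genes is the biological explanation that the design names, and remains a hypothesis.

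Endothelial markers were higher and stellate and fibrosis genes lower with FSH. A lower share of hepatocytes would raise both, and is argued against because the 2 medians moved apart by 0.49 (SE 0.16). Blood left in the tissue stays open for the endothelial rise: with the level of Hbb in the model the coefficient of FSH was 0.19 (SE 0.19), compared with a difference of 0.26 without it. A change in the endothelial or stellate cells themselves was not tested.

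Regrouping the 9 animals into other sets of 4 and 5 gave a measure of chance over 100 splits. No other split tried gave as many genes higher (3 in the real split, at most 1 in the others, 1 split in all). This argues against chance for that count but does not exclude it. Only 100 of 126 possible splits were run, and even all 126 would be too few to exclude chance. With both directions counted, the real split (3 higher, 1 lower) stood out less, as another split gave 1 higher and 2 lower. The count of genes higher is also small, and it was 0 without vehicle replicate 1, vehicle replicate 4, FSH replicate 1 or FSH replicate 3. For genes lower chance stays open, since 7 splits gave as many (1 in the real split, at most 2 in the others). It stays open for the number of lists too, as 40 splits gave 8 or more and the highest other gave 17. Why so many lists passed in other splits was not tested. Among the 8 lists the estimated correlation ran from −0.087 (female-type genes) to 0.468 (respiratory chain genes). Only that of female-type genes lay below the preset of 0.01, so the preset may make camera p-values too small. For the fatty acid oxidation list, the real split had the smallest camera p (2.59e-12), 1 split in all, but the next was 2.63e-12, from a split that set 4 vehicle animals against the FSH group and the remaining vehicle animal.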

How the results depend on the processing

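Thinning the libraries was chosen only after the result was seen. The counts at FDR 0.05 were 3 genes higher, 1 lower and 8 lists. At FDR 0.10 they were 9 higher and 3 lower. With a log2 fold change of at least 1 there were 0 lower, and Acot4 fell just short at 0.998. DESeq2 called 109 higher and 67 lower, and limma-voom called 6 genes in total, 2 of them lower. There were 0 lower with total counts alone (3 genes in total), without a filter (3 in total) and with 1 surrogate variable (2 in total). With the replicate number as a block, 5 genes were higher and 0 lower. The numbers share only a label: deviations of same-numbered animals correlated between −0.041 and 0.035, and 0 of 4 FSH animals matched best with its own number. Leaving out each animal gave 0 to 4 genes higher, 0 lower throughout and 7 to 16 lists. In 4 of these fits 0 genes passed in total, while 1100 to 1269 genes had an unadjusted p under 0.05. Lists past the threshold were 0 with an estimated correlation and 0 in fry's directional test, whose own construction allows for correlated genes. The causes of these changes were not tested.

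None of the 4 called genes reversed. The fold change of Ghr was −0.037 in limma-voom. Leaving out each animal gave −0.175 to 0.199 for Ghr, −0.195 to 0.084 for Igf1 and −0.025 to 1.113 for Timd4. The direction of a list's test reversed for cytokines (adjusted p = 0.947 at 1 CPM in 4 samples, 0.978 thinned), Kupffer cells (0.970, 0.918, and 0.255 with the surrogate variable), T, NK and B cells (0.645 with the surrogate variable) and hepatocytes (0.780 with the block). It also reversed on leaving out some animals for the lists that follow. Over all 9 such fits, reversed or not, adjusted p ranged from 0.198 to 0.971 for cytokines, 0.0236 to 0.999 for Kupffer cells, 0.222 to 0.917 for T, NK and B cells, 0.295 to 0.945 for hepatocytes, 0.00288 to 0.999 for cholesterol synthesis, 0.209 to 0.995 for the endoplasmic reticulum list and 0.29 to 0.987 for antioxidant genes. Without vehicle replicate 2, Kupffer cell markers passed in the reversed, downward direction (adjusted p = 0.0236). Cholesterol synthesis passed at 0.00288 without FSH replicate 3 and kept its direction there.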

Other observations

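Outside the fixed lists, genes named here were chosen after their values were seen. Adcy10, the soluble adenylyl cyclase that makes cyclic AMP, was at 8.84 ± 1.93 CPM with FSH and 2.57 ± 1.33 CPM with vehicle (log2 fold change 1.81, SE 0.36), and Pde4b, a phosphodiesterase that breaks it down, at 3.27 ± 0.952 and 7.57 ± 2.38 CPM (−1.22, SE 0.26). The potassium channel gene Kcnj15 was at 5.57 ± 0.792 and 16.2 ± 7.21 CPM (−1.54, SE 0.29). In each of the 3 genes the groups did not overlap, but none passed the threshold (edgeR adjusted p = 0.175, 0.185 and 0.175). Across all tested genes 490 (4.11%) had groups without overlap, where chance gives 1.59% on average, with a spread that was not measured.

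An unnamed locus, AABR07058124.2, was at 899, 50.5, 25.4 and 96.4 CPM in FSH replicates 1 to 4 and at 8.33 to 20.6 CPM in the vehicle libraries (edgeR adjusted p = 0.190). Lifr was at 170 CPM in FSH replicate 1 and Krt23 at 30.3 CPM, with group means of 3.59 and 0.894 CPM in the vehicle animals. The chaperone genes Hspa5 (−0.54, SE 0.20) and Hyou1 (−0.76, SE 0.29) were lower with FSH without passing (edgeR adjusted p = 0.364 and 0.373), and both were highest in vehicle replicate 3.

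As a hypothesis, the fatty acid oxidation genes may be part of a wider rise of targets of PPAR-alpha, a nuclear receptor that senses fatty acids. In 24 target genes outside the fixed lists, not examined before, 15 were higher and 9 lower (median 0.10, fry p = 0.0365, upward, and exact permutation p of the median = 0.0635). Pex11a (0.77), Mlycd (0.27), Nudt7 (0.39) and Ech1 (0.66) passed when adjusted over the list alone, but camera with an estimated correlation did not separate the list from other genes (p = 0.106). Adjusted over the 2 lists tested in this way, the fry value was 0.0731. The criterion set in advance was thus met only before adjustment, and the hypothesis stays undecided.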
